A study of Mus musculus with 2 samples.

How the data were processed

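RNA of the hypothalamus was measured on 2 Affymetrix expression arrays, 1 for mice lacking Crtc1 and 1 for wild-type mice. Per the labels, the animals were males of 12 weeks that had been without food for 18 h and then had food again for 6 h. RNA was extracted with Trizol, treated with DNase and cleaned on columns. Per the series design text, RNA of 3 mice per genotype was mixed in equal parts before hybridisation, so each group is 1 pooled sample. Per the labels' protocols, biotin-labelled cRNA was made from 30 ug of total RNA. The mouse strain and the way the Crtc1 allele was made are not given in the sources used here.

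The deposited values are linear probe-set signal intensities, 1 value per probe set and array. The algorithm that summarised the probes, its version and the scaling are not given in the sources used here. From the values themselves, the mean without the lowest and highest 2% of probe sets was 200.0 on both arrays, while the medians differed, so the authors' values had been scaled by 1 factor per array and had not been quantile normalised. Signals ran from 0.1 to 10463 in the knockout pool and from 0.1 to 11069 in the wild-type pool. Such a scaling fixes the overall level and leaves the dimmest values noisy, and a low linear signal can give a large ratio by chance. A cross-hybridising probe or a DNA variant under a probe would also move a signal without any difference in the transcript.

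The table held 45101 probe sets, of which 64 are the manufacturer's controls and were left out of all gene values. Genes were named from GEO's platform annotation, with symbols updated by Entrez gene ID through the RefSeq gene table of assembly GRCm38.p6. Of the other 45037 probe sets, 34945 were paired with 1 gene, 932 with several and 9160 with none in the table used. Of the probe sets with 1 gene, 34741 had an identifier in the RefSeq table. No gene was named from a probe set paired with several. Of 418 genes on the fixed lists, 37 had no probe set paired with that gene alone, among them some central to the question, and these are not reported here. The RefSeq table was otherwise used only for the order of protein-coding genes along a chromosome.

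The medians of the 2 arrays differed by 0.06 on the log2 scale, under the limit of 0.1 set beforehand, so the deposited scaling was kept. Each array was floored at its 30th percentile, a signal of 20.5 in the knockout pool and 20.2 in the wild-type pool, and then put on the log2 scale. A probe set counted as measured where its mean log2 signal over both arrays was at or above the median of all such means, which kept 22519 probe sets and 11312 genes. A gene took the value of its measured probe set with the highest mean signal. Differences are knockout minus wild type on the log2 scale, and folds are the same differences on the linear scale.

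With 1 array per group no test between genotypes was possible, no p-value is given and no difference has a replicate check. The number of arrays limits the precision. The only error that can be measured is that of the array, taken as the SD between measured probe sets of one gene. It was 0.32 on the log2 scale below a mean log2 signal of 7, 0.26 from 7 to 8, 0.23 from 8 to 9, 0.21 from 9 to 10 and 0.16 above 10. This error holds no spread between mice, and it can hold real differences between transcripts of one gene.

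The groups, gene lists, thresholds and the rule for named genes were fixed before the data were examined. Named genes were the members of the CRTC and CREB family; the 10 genes with the largest difference each way, above the floor on both arrays and with all measured probe sets of one sign; the 5 each way with the largest mean difference among genes with at least 2 measured probe sets, all of one sign and each differing by at least 0.5; up to 4 members of each list with the largest difference; feeding and reproduction genes central to the question; and genes within 10 genes of Crtc1 that differed at least 1.5-fold. Clone-named transcripts were to be counted without a name, and none differed at least 2-fold. The 34 lists covered the CRTC and CREB family, textbook CREB targets, early response genes, feeding, reproductive, neuroendocrine, monoamine, clock, glucocorticoid, heat shock, lipid synthesis, respiratory chain and interferon genes, markers of brain regions and cell types, sex-linked genes and genes that vary between mouse strains. For each list the median difference of the measured members was set against 10000 random lists of the same size, each member replaced by a gene within 100 ranks of its mean signal. A list stood apart where its median lay outside the central 95% of those lists.

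Alternatives were median centring, quantile normalization, signal-dependent loess (span 0.3), floors at the 10th and 50th percentile, a pseudocount of 16 with no floor, no filter on dim probe sets, a filter at the 70th percentile, the mean of all measured probe sets of a gene, leaving out probe sets whose ID ends in _s_at, _x_at or _a_at, thresholds of 1.5-fold and 3-fold, and windows of 5 and 20 genes around Crtc1. The code was tested on simulated data made from the real signals, for 11317 genes of the knockout against the wild-type array. It recovered as at least 2-fold 96% of genes given a log2 difference of 1.5 and 99% of those given 3, and called 0.198% of unaltered genes. The simulated noise per array followed a curve set by hand to fall with signal, so these rates depend on that choice. Of 200 simulated lists with no shift, 4% fell outside the central 95%. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.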

Results

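Transcript levels were compared between the hypothalamus of refed Crtc1 knockout mice and that of refed wild-type mice. Crtc1 is a coactivator of the transcription factor CREB, and the study's title places it in the control of energy balance and fertility. Each genotype was represented by 1 array of RNA pooled from 3 males. The median probe-set signal was 54.4 in the knockout pool and 52.2 in the wild-type pool, and log2 signals of the measured probe sets correlated between the arrays at r = 0.984, a correlation across probe sets, which are not independent replicates. Ratios of 3' to 5' control signals, which rise when RNA is degraded, were 1.47 and 1.25 for actin and 0.863 and 0.873 for Gapdh in knockout and wild type. They were 3.85 and 5.87 for the transferrin receptor and 2.60 and 1.68 for pyruvate carboxylase. Hybridisation spike-ins differed by -0.01 to 0.14 on the log2 scale.

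The Crtc1 signal was lower in the knockout pool. Probe set 1434476_at read 85.1 against 631 in the wild type, which is 7.42-fold lower (log2 difference -2.89, array error 0.26). Probe set 1458443_at read 31.5 against 209 and was 6.64-fold lower (-2.73). A dimmer probe set, 1446533_at, was at the floor in the knockout pool and read 38.4 in the wild type, below the limit for a measured probe set. The direction matches the labels, although where these probe sets lie relative to the altered part of the gene is not given in the sources used here. The 8 other measured members of the CRTC and CREB family differed by at most 1.24-fold by their brightest probe sets. Crtc2 and Crtc3, the paralogs of Crtc1, differed by -0.23 and 0.04, and Creb1 and Crem, which encode CREB-type transcription factors, by 0.06 and -0.14. The acetyltransferase genes Crebbp and Ep300 differed by 0.09 and -0.01. Sik2 and Sik3, which encode kinases that hold CRTC proteins in the cytoplasm, differed by 0.31 and 0.01. A dimmer measured probe set of Crebbp was 1.51-fold higher and one of Crem 1.46-fold lower. The probe sets of Crtc3, Sik2 and Sik3 had opposite signs, and the signs of Crtc3, Creb1, Sik3 and Ep300 were not kept under every scaling. The median of the family was 0.01, at percentile 56.1 of its random lists.

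Across the hypothalamus few transcripts differed strongly between the pools. Among genes whose measured probe sets shared one sign, the lowest besides Crtc1 were Apoc1, an apolipoprotein gene, at 3.94-fold lower, and Slc5a5, which encodes the sodium and iodide symporter, at 3.00-fold lower. Dctd, Micu3, Depp1, Med18, Haus8, Cited1 and Lamb2 followed at 2.58-fold to 2.27-fold lower. The highest were Igf2bp3, an RNA-binding protein gene, at 6.33-fold, and the chemokine-like factor Cklf at 4.01-fold. Myl4, a myosin light chain, was 3.62-fold higher and Plvap, a protein of the diaphragms of fenestrated endothelium, 3.20-fold higher. Klhl4, Xrn1, Mtrr, Lpl, Spata24 and Zfp799 followed at 2.85-fold to 2.35-fold. Lpl, which encodes lipoprotein lipase, was 2.39-fold higher by its brighter probe set and 1.35-fold by the other, with a mean of 0.85 on the log2 scale, under 2-fold.

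Of 11312 measured genes, 49 (0.433%) differed at least 2-fold, 30 higher and 19 lower in the knockout pool, and none of these was at the floor on either array. The excess of higher genes depended on the scaling, since median centring gave 23 higher and 23 lower and signal-dependent loess 23 and 22. At 1.5-fold, 233 genes were higher and 163 lower, and 78.1% of genes lay within 1.2-fold. The SD of the differences over all measured genes was 0.25 on the log2 scale. The signal of Igf2bp3 in the wild-type pool was 21.8, close to the floor of 20.2, and its log2 difference of 2.66 was 1.40 with a floor at the 50th percentile. With that floor its top rank was lost, since Cklf was at least 1.70 in every setting that measured it. With that floor Spata24, which read 35.5 in the wild-type pool, went from 1.26 to 0.70, under 2-fold, and it was 0.97 with a pseudocount. Apoc1, named above as the lowest besides Crtc1, read 36.5 in the knockout pool by 1 probe set. Its log2 difference of -1.98 was as small as -1.40 among the settings. There its rank was lost, since Slc5a5 was -1.41 or lower in every setting that measured it. Of the 20 genes with the largest differences and probe sets of one sign, 16 rested on 1 measured probe set. The position of 8 of these 20 genes, Crtc1 included, was on the chromosome of Crtc1, which held 5.22% of the measured genes, and of the 49 genes past 2-fold it held 11.

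**Figure D1:**
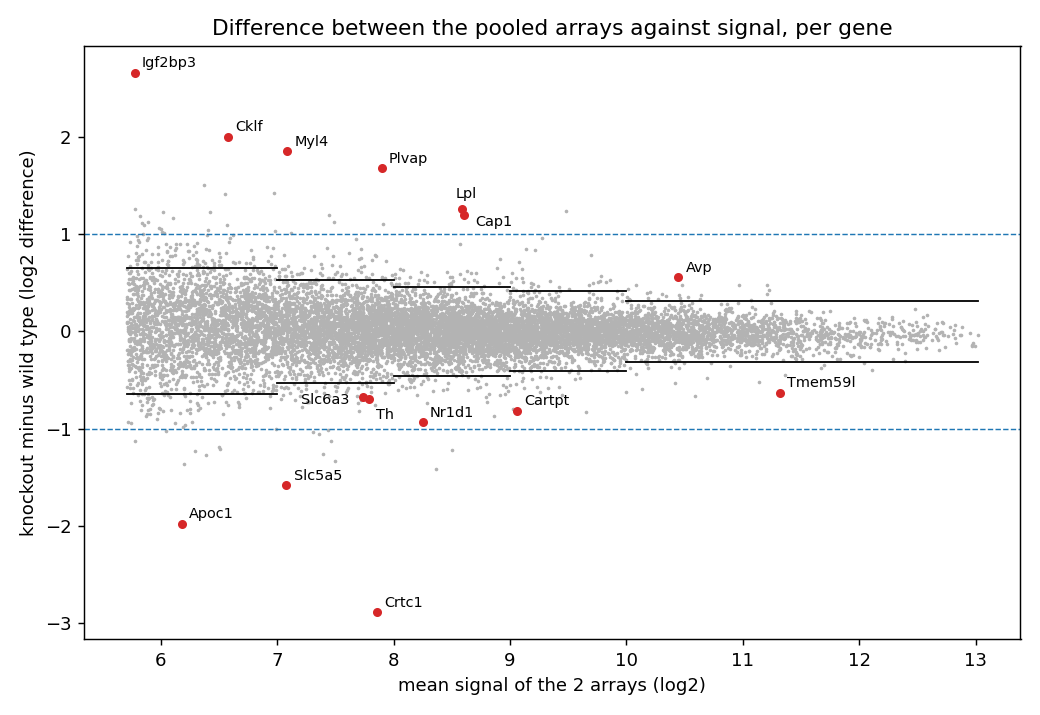
Knockout minus wild type (log2 difference, y axis) against the mean log2 signal of the 2 arrays (x axis) for each measured gene, with genes discussed in the text in red. Black lines mark 2 times the array error in each signal range, from 0.32 among the dimmest genes to 0.16 among the brightest, and dashed lines mark 2-fold; Crtc1 at -2.89 lies lowest.

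Genes seen by several probe sets gave repeat readings of the same pools. Slc5a5 was 3.00-fold and 2.82-fold lower by its 2 probe sets. Cap1, which encodes an actin regulator bound to adenylyl cyclase, was 2.29-fold and 3.05-fold higher, and Myl4 was 3.62-fold and 1.98-fold higher. On a list of striated muscle genes written after the data were seen, all 9 measured members were higher. Without Myl4, Tnnc1 and Smyd1, which prompted the list, the median of the other 6 was 0.30, under the upper bound of 0.34 of their random lists by less than its array error of 0.16. By the mean of their probe sets, Timm50, a subunit of the mitochondrial protein import machinery, differed by -0.97, Cabp7 by -0.94 and Lbh by -0.76. Ddit4l differed by 0.89, Aif1l by 0.88 and Smyd1, a muscle methyltransferase gene, by 0.77. In all, 19 genes had every measured probe set of one sign and at least 0.5 apart between the pools. Of 5199 genes with at least 2 measured probe sets, 16 differed at least 2-fold by the brightest, and in 12 of these (75%) the next probe set had the same sign. The count was 8 with each alternative scaling, where fewer genes passed 2-fold, so by itself it does not measure the agreement of probe sets. Over all 5199 genes the share of equal signs was 54.9%. In 4 of the 16 the next probe set differed at least 1.5-fold in the same direction.

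Among genes of feeding and energy balance, Cartpt stood out. It encodes the anorexigenic peptide precursor CART and read 402 in the knockout pool against 707 in the wild type, 1.76-fold lower (-0.82, array error 0.21, 1 probe set). Npy, whose peptide drives feeding, differed by -0.13. Pomc, the precursor of melanocortins, was 1.27-fold lower by its brighter probe set and 1.56-fold higher by the other, so it had no settled direction. Gal was 1.41-fold lower and Nts 1.40-fold higher. Of 23 feeding neuropeptide genes 14 were measured, with a median of -0.07, 8 lower and 6 higher (percentile 8.1). Of 24 feeding receptor and signalling genes 14 were measured, 11 lower and 3 higher, with a median of -0.07 (percentile 9.19). The one past 1.5-fold was Npy1r, a receptor for neuropeptide Y, at 1.62-fold higher, and it lies 53 genes from Crtc1. Cnr1, the cannabinoid receptor gene, was 1.32-fold higher by its brightest probe set, and the mean of its probe sets was -0.16.

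The measured genes of the reproductive axis did not stand apart as a group. Only 8 of the 16 genes on the list were measured, 5 lower and 3 higher, with a median of -0.07 (percentile 17.1). The other genes of the list are not covered by this result. Tac2, which encodes neurokinin B, was 1.26-fold lower, Pdyn, which encodes dynorphin, 1.22-fold lower, and the oestrogen receptor gene Esr1 1.16-fold higher. The differences of Pdyn and Esr1, -0.28 and 0.21 on the log2 scale, were within their array errors of 0.32 and 0.26. Among secreted neuroendocrine hormones, Avp and Oxt, the vasopressin and oxytocin genes, were 1.47-fold and 1.39-fold higher, while Chga, which encodes the granule protein chromogranin A, was 1.54-fold lower. The median of the 10 measured hormone genes was 0.08 (percentile 95.3).

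Textbook CREB targets were slightly lower as a group. Of 16 measured members, 12 were lower and 4 higher, and the median of -0.12 stood at percentile 1.33 of its random lists. Of the 20 genes on this list, 15 are also on another. Cartpt was the one member past 1.5-fold. Fos and Nr4a1, both induced early by neuronal activity, were 1.30-fold and 1.26-fold lower, and Nptx2 was 1.42-fold higher. Without Cartpt the median was -0.10 and lay inside the central 95% (percentile 3.11), a setting chosen after seeing the data, and with no filter on dim probe sets it also lay inside (percentile 3.12). Leaving out the early response genes, likewise chosen after seeing the data, put it inside too (percentile 4.35). The 18 measured early response genes had a median of -0.08 (percentile 4.83), with 10 lower and 8 higher. Their largest differences went both ways. Nr4a3 was 1.42-fold lower, Egr3 1.52-fold higher, Npas4 1.41-fold higher and Gadd45b 1.53-fold lower, the last with probe sets of opposite sign.

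The monoamine list stood furthest apart of the 33 lists with measured members, by percentile in the main setting. The choroid plexus list stood further apart with averaged probe sets (percentile 0.02 against 0.08), with no filter (0.09 against 0.11) and with the pseudocount (0.04 against 0.05). The monoamine median was -0.33 (percentile 0.05) over 7 genes, 4 lower and 3 higher. This median is the value of Slc18a2, and the next member up, Maoa, differed by 0.03. The median thus sits at the gap between the lower and the higher genes, and leaving out 1 lower gene alone was not tried. The 4 lower genes make or carry dopamine. Th, the rate-limiting enzyme of catecholamine synthesis, was 1.62-fold lower (array error 0.26), the dopamine transporter gene Slc6a3 1.60-fold lower, Ddc 1.29-fold lower and the vesicular transporter gene Slc18a2 differed by -0.33. Hdc, which makes histamine, was 1.28-fold higher by its brighter probe set and had a probe set of the opposite sign (mean 0.03), and the remaining members, the monoamine oxidase genes, were within 1.04-fold. On a list of 16 midbrain dopamine cell genes written after these values were seen, 5 were measured. Their median was -0.23, below the lower bound of -0.21 of their random lists (percentile 1.82) by less than its array error of 0.16. Each of the 5 genes differed by less than its own array error.

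Choroid plexus markers were lower in 9 of 10 measured members, with a median of -0.27 (percentile 0.1). Folr1, a folate receptor gene, was 1.49-fold lower, Kl, which encodes klotho, 1.46-fold lower, Sostdc1 1.35-fold lower and the water channel gene Aqp1 1.30-fold lower. The brightest members, Ttr and Igf2, differed less, by -0.15 and -0.10, within their array errors of 0.16 and 0.21. Cortex and hippocampus markers were higher in 8 of 12, with a median of 0.13 (percentile 99.0). Neurod6 was 1.57-fold higher and Lamp5 1.28-fold higher, while Emx2 was 1.37-fold lower. Neurod2 was 1.30-fold lower by its brighter probe set, and the mean of its probe sets was -0.07. This shift was lost when probe sets of a gene were averaged (median 0.05, percentile 82.6). Microglia markers were higher in 8 of 11, with a median of 0.14 (percentile 98.0), led by Trem2 at 1.62-fold, P2ry12 at 1.24-fold and the complement gene C1qb at 1.22-fold. That shift was lost in 3 of 10 settings, with percentiles down to 90.4.

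In all, 5 of the 33 lists lay outside the central 95% of their random lists, 3 lower and 2 higher. If genes varied independently, 1.65 lists would. Random lists hold unrelated genes, whereas members of a list can vary together between 2 single pools, and some lists share members. The number expected without an effect of genotype may therefore be higher, and the percentiles may look too extreme. Close to the upper bound were sterol and fatty acid synthesis genes (median 0.07, percentile 97.4), with Idi1 1.34-fold higher, and striatum markers (0.12, percentile 97.0), with Rgs9 1.43-fold higher. Of the 314 measured list genes, 2 differed at least 2-fold, Crtc1 and Pdk4. Pdk4, a brake on pyruvate oxidation that glucocorticoids induce, was 2.06-fold higher (1.04), a difference of 0.98 to 0.99 and so under 2-fold with each alternative scaling and of 0.88 with a pseudocount, while its list had a median of -0.03 (percentile 39.4). Nr1d1, the circadian repressor known as Rev-erb alpha, was 1.91-fold lower (-0.93, array error 0.23), while the 15 clock genes had a median of 0.02 (percentile 59.4). Heat shock genes had a median of -0.01 (percentile 61.4), with Bag3 1.47-fold lower. The 27 respiratory chain genes had a median of -0.05 (percentile 9.66), with 18 lower.

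Markers of neurons and of most glia differed little. The medians were -0.04 for pan-neuronal markers (percentile 40.1), -0.02 for GABA neuron markers (percentile 35.7) and 0.11 for the 2 measured glutamate neuron markers (percentile 77.2). Hypothalamus regional markers had a median of 0.04 over 4 genes (percentile 51.2), and thalamus markers 0.00 over 12 (percentile 59.3). Astrocyte markers had a median of 0.03 (percentile 86.3), myelin markers 0.03 (percentile 86.0) and oligodendrocyte precursor markers 0.06 (percentile 74.5). Tanycyte markers had a median of -0.07 (percentile 20.5), with the intermediate filament gene Nes 1.52-fold lower, and ependymal markers -0.03 (percentile 25.6), with Ccdc153 1.56-fold higher. Endothelial markers had a median of 0.09 (percentile 80.6) and meningeal and fibroblast markers 0.12 (percentile 81.7). Red blood cell genes had a median of 0.12 over 2 genes (percentile 59.8) and interferon-induced genes 0.06 over 2 (percentile 58.2). None of the 11 pituitary markers was measured. Both pools came from males, and of the Y-linked genes Uty was 1.65-fold higher, Kdm5d 1.12-fold higher and Eif2s3y 1.08-fold lower. Genes that vary between mouse strains had a median of 0.09 over 5 (percentile 92.4), and Nnt, Wdfy1, Glo1 and Erdr1 differed by 0.13, 0.22, -0.17 and 0.09, Wdfy1 with probe sets of opposite sign.

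**Figure D2:**
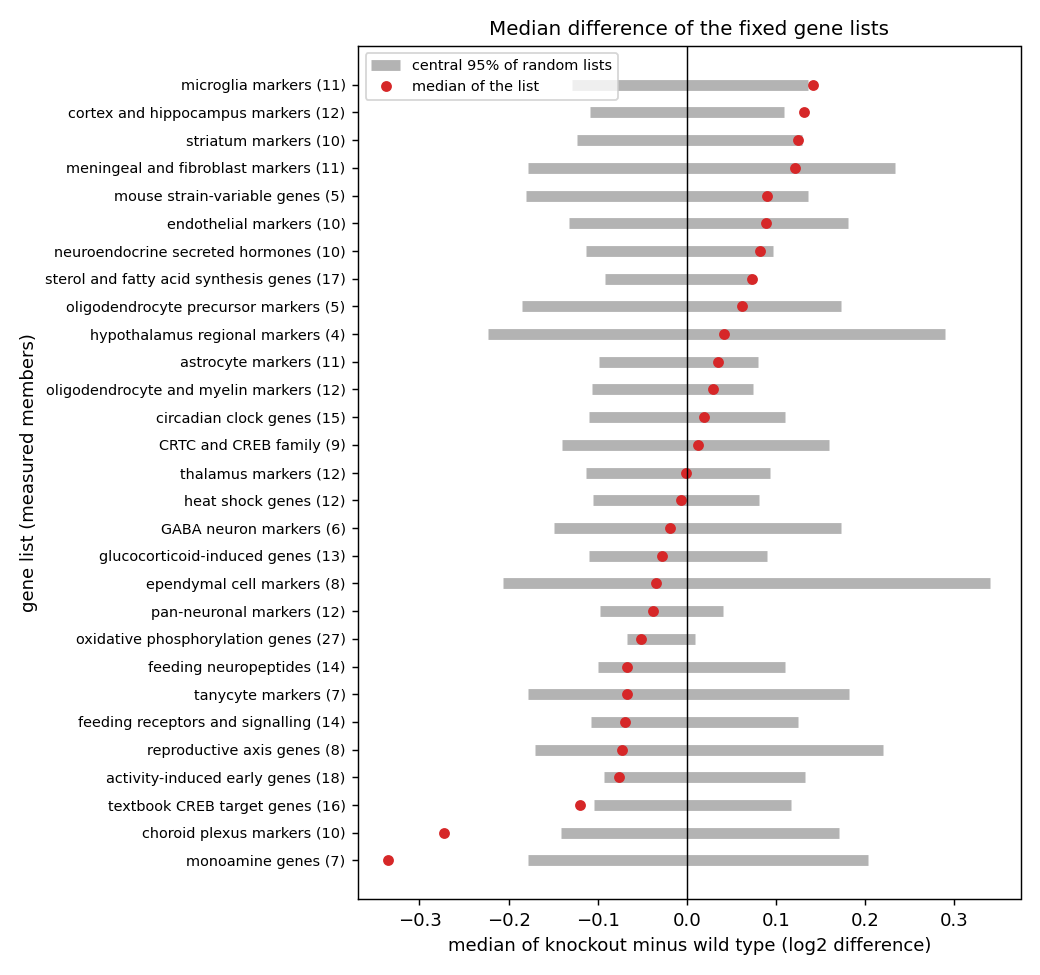
Median of knockout minus wild type (log2 difference, x axis) for each fixed list with at least 4 measured members, whose number stands in parentheses (y axis). Red points are the medians and grey bars the central 95% of 10000 random lists matched on signal; the monoamine list at -0.33 and the choroid plexus list at -0.27 lie furthest from their bars.

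Several neighbours of Crtc1 also differed between the pools. Among the 10 protein-coding genes on either side, in the order of assembly GRCm38.p6, 13 were measured and 3 (23.1%) differed at least 1.5-fold, against 3.50% of all measured genes. Upf1, which encodes a helicase of nonsense-mediated decay, was 1.80-fold lower (-0.85, array error 0.32) and lies 2 genes from Crtc1. Tmem59l, 2 genes away on the other side, read 2054 against 3181 and was 1.55-fold lower (-0.63, array error 0.16). Sugp2 was 1.65-fold higher by its brightest probe set, but its probe sets had opposite signs and it was -0.35 without the probe sets that can match several transcripts. With 5 genes on either side 2 of 5 measured genes passed 1.5-fold, and with 20 genes 4 of 24. None of the genes in these windows passed 2-fold. Among the genes of largest difference, Slc5a5, Haus8, Plvap and Lpl also lie within 50 genes of Crtc1.

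**Figure D3:**
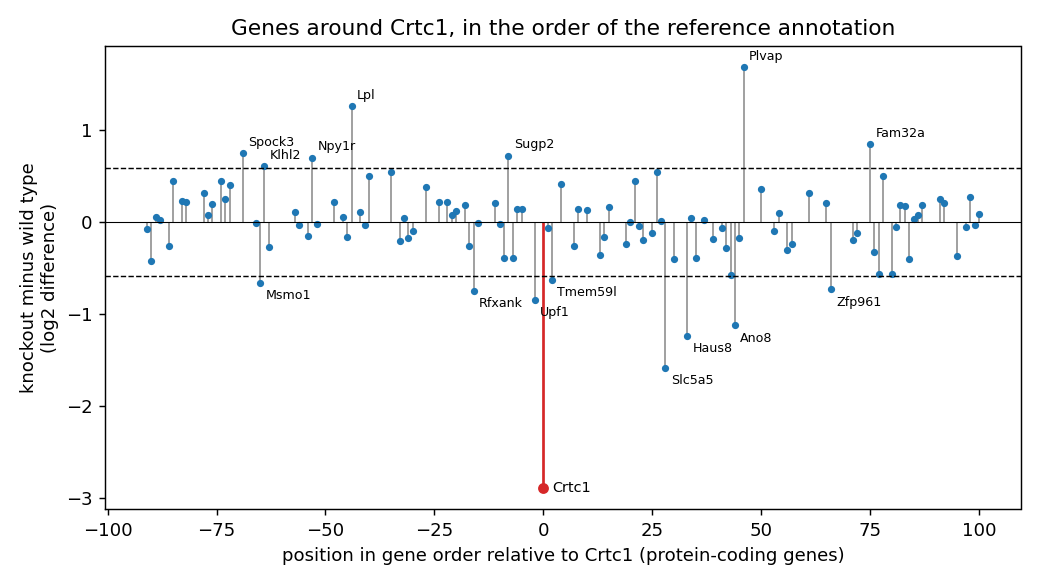
Knockout minus wild type (log2 difference, y axis) for each measured gene within 100 protein-coding genes of Crtc1, by position in gene order (x axis), with names at 1.5-fold or more (dashed lines), a range drawn after the data were seen. Crtc1 is red at -2.89, and Slc5a5, Haus8 and Ano8 lie below -1 while Plvap and Lpl lie above 1.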

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

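Among 2705 measured probe sets that the annotation did not pair with 1 gene, and which enter no gene value, 12 were at least 2-fold higher in the knockout pool and 13 at least 2-fold lower. These readings were singled out because they lie outside the genes compared above. Together they make 0.924% of the unnamed probe sets, against 0.570% of the named measured ones. They were not assigned to genes here, and no explanation for them was tested.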

How the results depend on the processing

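No paired analysis was possible because each genotype was 1 pooled array, so no sample could be left out either. The settings without genes near Crtc1, without Cartpt, without early genes and with a window of 50 genes were chosen after seeing the data. Crtc1 stayed lower in all settings tried, from -2.95 to -2.68. The counts of genes past 2-fold (30 higher, 19 lower) depended on how dim probe sets were treated. Without a filter they were 132 and 109, and with a filter at the 70th percentile 7 and 7. A floor at the 50th percentile gave 18 higher, and a pseudocount of 16 gave 15. At 1.5-fold they were 233 and 163, and at 3-fold 4 and 3. Quantile normalization gave 25 and 22. Leaving out genes within 100 of Crtc1 gave 28 and 15. Between 14 genes (70th percentile filter) and all 49 remained past 2-fold per setting. The filter removes genes by construction; for the other settings the cause was not tested. Genes whose next probe set shared the sign (12) numbered 8 with each alternative scaling, 7 with the pseudocount, 34 without a filter and 3 with the 70th percentile filter. These counts also follow the number of genes past 2-fold in each setting.

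Genes past 1.5-fold beside Crtc1 numbered 3, and 9 with 50 genes on either side, where no filter gave 12 of 74 and the 70th percentile filter 5 of 43. Sugp2 turned from 0.72 to -0.35 without _s_at, _x_at and _a_at probe sets. Of 1482 values of named genes under alternatives, 1458 moved by less than the array error. Part of this follows from the settings, since median centring moves genes above the floor by about 0.06 and a lower floor leaves them as they were. The sign differed from the main value in 17, over 12 genes. Of these genes Sugp2 alone was past 1.5-fold in the main setting, and Pomc, Cnr1 and Sox9 differed in sign when probe sets were averaged. Of 330 list medians, 288 moved by at most 0.25 of the width of their random range, 42 moved further and none of the 5 lists that stood apart turned. Between 4 and 7 lists stood apart per setting. The monoamine and choroid plexus lists did so in 10 of 10 settings, CREB targets and cortex in 9 and microglia in 7. None of these settings left out a single lower monoamine gene to see whether the median held. The floor at the 10th percentile left the percentiles of these 5 lists as they were. Median centring moves a list and its random lists alike, so neither setting could have changed these calls much. Without the early genes the CREB target median was -0.10 (percentile 4.35). The array error was 2.04 times larger among the dimmest genes than among the brightest, and whether low signal explains the values that moved was not tested.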

Other observations

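Several striated muscle genes read higher in the knockout pool. Beyond Myl4, the cardiac and slow-muscle troponin gene Tnnc1 was 2.30-fold higher. Smyd1, a muscle methyltransferase gene, was 2.02-fold higher and 0.96 on the log2 scale, under 2-fold, with each alternative scaling. Myh7, a slow and cardiac myosin heavy chain, was 1.49-fold higher and the skeletal actin gene Acta1 1.40-fold. The brightest of them, Myh7, read 310.1 against 208. A list of muscle genes was written after Myl4, Tnnc1 and Smyd1 had been seen among the largest differences. Its 6 other measured members were all higher, with a median of 0.30 inside the central 95% of their random lists (upper bound 0.34, percentile 95.48), and Myl3, Tnnt2 and Actn2 differed by less than their array error.

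Beyond the genes next to Crtc1, a wider stretch of its chromosome held further differences, among genes chosen after their values were seen. Ano8 was 2.18-fold lower and Haus8 2.35-fold lower, each by 1 probe set. Rfxank was 1.68-fold lower by its brighter probe set and had a probe set of the opposite sign. Further out, Fam32a was 1.79-fold higher by its brighter probe set and 1.12-fold by the other. Spock3 and Zfp961 were 1.68-fold higher and 1.66-fold lower, and Msmo1, a sterol synthesis gene, was 1.58-fold lower.

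Of the tests that follow, those on the genes around Crtc1 were chosen after the result was seen. The windows of 5, 10 and 20 genes were planned, whereas that of 50 was picked after windows of up to 200 genes had been looked at. The lists for midbrain and muscle were written after the patterns but before their other members were examined. Bounds for both were set beforehand, and the demand that a median clear its bound by more than its own array error was added after the values were seen. The random lists come from the same arrays and already hold array error, so this demand counts that error again.

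Within 50 genes of Crtc1, 9 of 60 measured genes (15%) differed at least 1.5-fold and 5 at least 2-fold. Draws of genes of matched signal gave 1.85 on average and at most 5 in the central 95%. With the 70th percentile filter 5 of 43 genes passed against at most 2 in the draws. With the 9 seen this argues against dim-signal noise, although the window was picked after the data were seen. In the planned window of 10 genes, 3 of 13 measured genes passed 1.5-fold against at most 2 in the draws. The planned windows of 5, 10 and 20 genes held no gene past 2-fold, so the windows were compared over all 6 sizes and both thresholds looked at. Of 20857 genes on other chromosomes, 1 (0.00479%) had a window as extreme, which argues against such windows being common in the genome. Windows of nearby genes overlap, so this share does not count independent stretches. DNA of another mouse strain carried along with the targeted allele may be the source but stays open. The planned window of 10 genes (23.1% past 1.5-fold) exceeded its draws in 8 of 10 alternatives and in 2 did not. An excess in all of them would not have told strain DNA from other causes, since the strain is not given. Within 200 genes of Crtc1, 24 genes passed 1.5-fold and 8 passed 2-fold. Around genes on other chromosomes such windows held at most 13 and 4. A local effect of the altered locus was not tested. Whether transcripts or only single mismatched probe sets differed cannot be told apart, because just 4 of the 9 near genes past 1.5-fold had several measured probe sets, and in 2 of the 4 (50%) these had one sign.

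The lower dopamine genes (median -0.52 over Th, Ddc, Slc6a3 and Slc18a2) may reflect less midbrain tissue in the knockout dissection, or fewer transcripts in the hypothalamic dopamine cells. Of the genes on a list for midbrain dopamine cells, 5 were measured, each differing by less than its own array error, with a median of -0.23 (percentile 1.82). That lies past the lower bound of -0.21, which the rule as first set counted in favour of less midbrain tissue. The gap to the bound is less than the median's array error of 0.16. With that margin, added after the values were seen, the test decides nothing. The dissection and the genotype cannot be told apart here, since each genotype was 1 pool and several members, such as Calb1 at 0.13, are also expressed in the hypothalamus. An effect of the genotype on these cells stays open and was not tested.

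The higher muscle genes may come from striated muscle tissue in the knockout pool. Without Myl4, Tnnc1 and Smyd1, the median of the 6 remaining genes was 0.30. That lies inside the upper bound of 0.34, which the rule as first set counted against muscle tissue. The gap to the bound is less than the median's array error of 0.16. With that margin, added after the values were seen, the test decides nothing, so muscle tissue and genotype cannot be told apart. No biological explanation was tested.

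For the lower choroid plexus list, 2 tests were run after its values were seen and are given as values only. The SD of the 10 members was 0.21, or 0.795 times that given by the array error, and the ependymal list had a median of -0.03.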
